A study of Mus musculus with 9 samples.

How the data were processed

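The series holds 9 RNA-seq samples of splenic CD3+ T cells from 3 C57BL/6 mice, with 1 sample per mouse in each of 3 media and 4 h of incubation. Per the labels' protocols, RNA was extracted with a silica column kit, cDNA was made with SMART-seq v4, libraries were made with Nextera XT and sequencing was on a NovaSeq. The submitters' processing notes name FastQC, Trimmomatic, featureCounts and DESeq2 without versions, and the builds GRCm39, GRCh38 and hg38, with no role for each. The aligner, the annotation and the strand setting of the counting are not given in the sources used here. The labels say that the cells came from mouse spleens, and no reason for the human builds was found.

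There are 2889 genes and 9 samples in the sample table. Its values are a normalized signal per gene, not coverage: the authors divided read counts by 1 size factor per sample, as the values show, since 100% of them are whole multiples of the sample's smallest step within 0.001 reads. Whole reads were recovered from those steps, 6522742 to 13758643 per sample over the listed genes. The authors' deposited cluster number of each gene runs from 1 to 4. The authors also deposited a table for each conditioned medium against unconditioned medium. Per the file headers these hold a mean signal, which equals the mean over all 9 samples, a log2 fold change with its standard error, a Wald score, and a p-value with its adjusted value. The deposited Wald score equals the log2 fold change less log2 of 1.5, over its standard error, within 6e-04, so the authors' p-value tests a change beyond 1.5-fold. The genes of the sample table are those of the authors' tables in the main: 2889 of the 3495 genes in those are listed, and no other gene is. How the authors' size factors were estimated is not given in the sources used here, and they were taken as deposited.

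The selection affects the measurements. A count of changed genes, a camera test and a median are relative to genes already chosen for changing, so they are not independent evidence of how broad a response is. Most gene lists had more members in the authors' adipocyte table than in their stromal table. This favours a larger change of those lists in adipocyte than in stromal medium. Most listed genes are lower in adipocyte medium, and a scaling built on the listed genes alone differs from the authors' scaling. cDNA primed at poly(A) tails favours polyadenylated transcripts, so values of histone and small nuclear RNA genes depend on priming. Nextera libraries do not keep strand, so reads of overlapping antisense genes cannot be told apart.

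Values were analysed as log2(value + 1) with limma-trend (limma 3.58.1 in R 4.3.3) over genes with a mean of at least 1 over all samples, which kept 2868 genes. A log2 fold change on this scale understates the change of low genes. All 9 samples were in 1 fit with the group as the only factor, and 3 contrasts were taken, adipocyte against unconditioned, stromal against unconditioned and adipocyte against stromal medium. The p-values were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. A count model had been planned in case of raw counts, and the normalized values called for limma, the planned test for that unit. With 3 samples against 3 an exact permutation test cannot go below 0.1, so no such test was made for single genes.

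Gene lists, 34 of them, were fixed before the data were examined: cytoskeleton, microtubules, adhesion, receptor signalling, activation, quiescence, type I and gamma interferon, cytokine STAT, NF-kB, TGF-beta, glucocorticoid, fatty acid oxidation, cholesterol, LXR, glycolysis, ATF4, unfolded protein, heat shock, NRF2, oxidative phosphorylation, ribosome biogenesis, proliferation, p53, trafficking receptors, effector genes and markers of B, myeloid, neutrophil, natural killer, erythroid, adipocyte, stromal and T cells. The 28 lists with at least 5 tested members were tested by camera with a preset correlation of 0.01 against the other selected genes, and again with the correlation estimated from the samples, under which 0 lists were called in any comparison (1, 2 and 0 lists at an unadjusted p under 0.05). Fry, which asks only whether the genes of a list move one way on balance, had adjusted p-values from 5.19e-07 to 0.276 in adipocyte against unconditioned medium. Some genes are on more than 1 list, so calls of different lists are not independent of each other.

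Named genes followed a rule set before the data were examined. For each comparison it took the 8 largest rises and 8 largest falls among genes past the threshold with the same sign in all 3 mice and outside the lowest 25% of means, leaving out unnamed models and pseudogenes. It added up to 4 members with the smallest adjusted p from each list that was called or held at least 5 changed genes, and 14 genes named in advance, of which 7 are in the sample table: Nr4a1, Klf2, Cpt1a, Plin2, Socs3, Isg15 and Cd3e. Socs3, a feedback inhibitor gene of cytokine signalling, was at 1.17 and 0.88 in adipocyte and stromal against unconditioned medium, and the difference of 0.28 between them (adjusted p = 0.0367) was weak. Its adjusted p was 0.17 and 0.109 without adipocyte replicates 1 and 3, 0.126 and 0.0511 without stromal replicates 1 and 3, 0.427 and 0.156 without replicates 1 and 3 in every group, and 0.068 with only the 2 groups compared; it was 1.12e-04 after rescaling. Named outside this rule, after their values were seen, are Car1, Gbp2, Cd74, Il13 and Il17a in adipocyte against unconditioned medium, Abca1, Car1, Cd8a, Cxcr4 and S1pr4 in stromal against unconditioned medium, and Adgre5, Irf8 and Psat1 in adipocyte against stromal medium. The genes named from the authors' deposited adipocyte table that the sample table does not hold were chosen in the same way.

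The replicate numbers pair the samples because the descriptions give the same mouse for the same number. Deviations from the group mean correlated within a mouse at 0.21, 0.06 and 0.11 for adipocyte with unconditioned samples, 0.26, 0.13 and 0.21 for stromal with unconditioned samples, and 0.18, -0.12 and 0.06 between the conditioned media. The fit with the mouse as a block was chosen as an alternative beforehand. Other alternatives were pseudocounts of 0.5 and 5, no filter, a mean of at least 10, fits of the compared groups alone, a fold of at least 1.5, an adjusted p under 0.01, leaving out the 100 most abundant genes, a rescaling by the median of ratios and leaving out each replicate. Chosen after seeing the data, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 (with nulls of no change and of 1.5-fold) were run on the recovered reads with the deposited size factors. The edgeR fit called 2784, 1685 and 2611 genes and the DESeq2 fit 2786, 1721 and 2606, where limma called 2787, 1655 and 2609.

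The test was tried on simulated data with 200 changed genes. These are far fewer than the genes called in the data, so the adjusted threshold was stricter there and its rates do not carry over to these comparisons. For adipocyte against unconditioned medium limma recovered 62.7% of 1.5-fold, 86.6% of 2-fold and 100% of 4-fold changes over 2855 genes, with 10 false calls of 176. For stromal against unconditioned medium it recovered 61.2%, 82.1% and 98.5% over 2856 genes with 7 false calls of 168, and for adipocyte against stromal medium 68.7%, 82.1% and 100% over 2853 genes with 12 of 179. The median standard error of a log2 fold change was 0.131, which sets the precision of single genes.

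The reference annotation at hand, GENCODE M21, is on GRCm38 and not on the GRCm39 of the notes. It was used by Ensembl identifier only, for gene class, exon number and overlaps, with 2863 of 2868 tested genes matched and 5 not, and no coordinates are given. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.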

Results

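T cells carrying CD3 were purified from the spleens of 3 C57BL/6 mice by negative selection, in which the other cell types are pulled out, and each mouse gave 1 sample for each of 3 media. The cells were kept for 4 h in RPMI that no cells had conditioned, in medium conditioned by adipocytes, or in medium conditioned by stromal cells. The series as a whole asks how the surroundings of T cells act on their cytoskeleton and on forces at the T cell receptor. RNA of the 9 samples was sequenced from SMART-seq v4 cDNA, which is primed at poly(A) tails and does not keep strand. The deposited sample table gave 2889 genes, and 2868 of them had a mean of at least 1 normalized count and were tested. Each of the 2889 genes was also in 1 or both of the authors' tables of changed genes. The genes had thus been selected on these same samples, and every count given here is over that selection, not over the transcriptome.

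Reads on the listed genes came to 6522742, 10675860 and 10534301 in the unconditioned samples of mice 1, 2 and 3. They came to 11408772, 13758643 and 7672064 in stromal medium and to 8343787, 11894701 and 11936703 in adipocyte medium. These sums are not whole library depths, which are not known here. The 100 most abundant listed genes took 32.8% to 33.3% of the normalized counts in unconditioned medium, 35% to 36% in stromal medium and 40.4% to 41.6% in adipocyte medium. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 10.22 to 17.06 between unconditioned samples, 30.08 to 90.46 between stromal samples and 34.85 to 96.65 between adipocyte samples, so no library was counted as a duplicate. The first principal component held 76% of the variance and the second 15.2%.

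**Figure D1:**
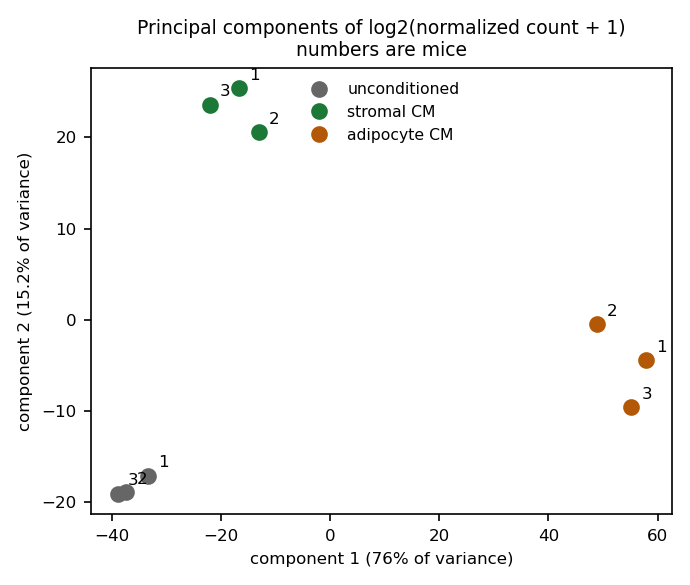
First 2 principal components of log2(normalized count + 1) over the tested genes, on axes of component score. Points are the 9 samples, coloured by medium and numbered by mouse; adipocyte medium samples lie apart on component 1 (76% of variance) and stromal medium samples on component 2 (15.2%).

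The first comparison asked what adipocyte conditioned medium did to the cells. The early activation list was higher, and so were single cytokine and chemokine genes. Interleukin 4 transcript (Il4, ENSMUSG00000000869), the signature cytokine of type 2 helper cells, went from 176 ± 28.6 normalized counts in unconditioned medium to 6462 ± 2263 in adipocyte medium (mean ± SD, n = 3), a log2 fold change of 5.14 (SE 0.26, limma adjusted p = 1.14e-08). Il21, a cytokine of follicular helper cells, rose by 4.97 on the log2 scale, Ifng, encoding interferon gamma, by 3.95, and the chemokine genes Cxcl2 and Ccl3 by 6.36 and 4.45. Nr4a1 (ENSMUSG00000023034), an orphan nuclear receptor gene induced by T cell receptor signals, rose from 26382 ± 1545 to 119120 ± 37150 (log2 fold change 2.12, SE 0.20, adjusted p = 5.09e-07). Gzmb, encoding the cytotoxic protease granzyme B, rose by 3.80, Junb, an AP-1 subunit gene, by 2.36, and Mmp10, a secreted metalloprotease gene, by 4.15. All 27 tested early activation genes, of 42 on the list, rose, by 0.81 to 4.45 with a median of 1.95. They stood above the other selected genes (camera adjusted p = 2.69e-10; adjusted p = 0.424 with an estimated correlation). Counts for each list are over tested members only, since the sample table holds only genes the authors called changed.

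**Figure D2:**
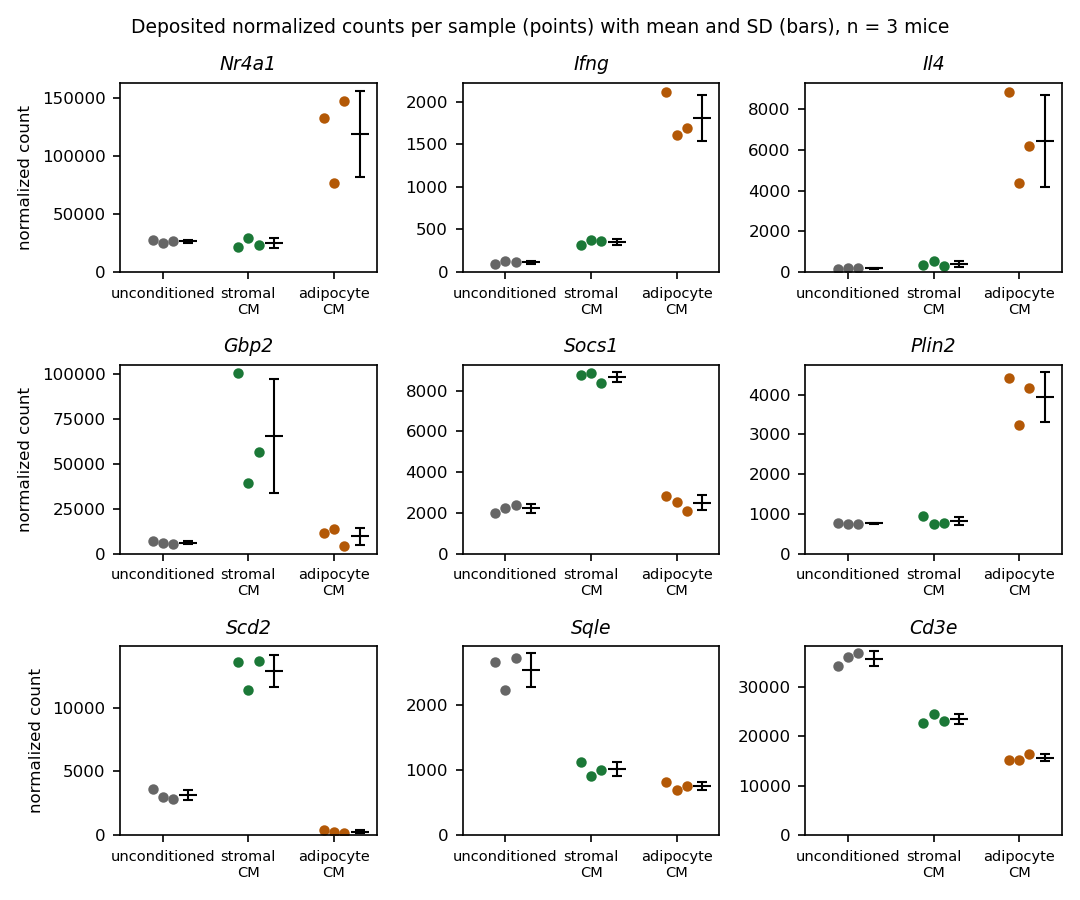
Deposited normalized counts (vertical axes, linear, from 0) of 9 genes in each sample by medium, with 1 point per mouse and bars for mean and SD (n = 3). Nr4a1, Ifng, Il4 and Plin2 are highest in adipocyte medium, Gbp2, Socs1 and Scd2 in stromal medium, and Sqle and Cd3e in unconditioned medium.

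Other inducible groups moved the same way in adipocyte medium. The lists share members, so their calls are not separate evidence. Cdkn1a is on the TGF-beta, glucocorticoid and p53 lists, and Batf is on the activation and STAT lists. All 12 tested NF-kB target genes, of 32 on the list, rose, among them Tnfaip3, which encodes a brake on NF-kB signalling, by 1.82 and Nfkb1, encoding the p105 precursor, by 1.27 (camera adjusted p = 2.72e-05). Of 17 cytokine STAT target and feedback genes, 15 rose and 1 fell, with Stat3 up by 1.58, the AP-1 family gene Batf by 1.62 and the kinase gene Pim3 by 1.55 (adjusted p = 2.06e-05). Glucocorticoid receptor targets rose in 12 of 14 cases and fell in 2 (adjusted p = 4.69e-04), and TGF-beta targets rose in 9 of 11 and fell in 2 (adjusted p = 0.00336). Within these 2 lists the inhibitor of differentiation gene Id1 rose by 3.20, the cell cycle inhibitor gene Cdkn1a by 2.03 and the chemokine receptor gene Cxcr4 by 1.37. All 8 tested heat shock genes, of 23 on the list, rose (adjusted p = 5.11e-04), most of all Hspa1a and Hspa1b at 3.71 and 3.68, near-identical genes whose reads the counting could split. Ribosome biogenesis genes rose in 9 of 10 cases (adjusted p = 0.00334), glycolysis and hypoxia genes in 7 of 9 with 1 lower (adjusted p = 0.00992), and p53 target and BCL2 family genes in 8 of 13 with 2 lower (adjusted p = 0.017). With an estimated correlation the adjusted p was 0.424 for the called lists of this paragraph, except the p53 list, where it was 0.468.

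In the interferon gamma response list 12 of 22 genes were higher, 1 was lower and 9 were not past the threshold (median 1.03, camera adjusted p = 0.00175; adjusted p = 0.591 with an estimated correlation). Rescaling by the median of ratios gave 21 higher and 1 lower (median 1.96). Irf1, a transcription factor gene of this response, rose by 1.47 and Cd274, encoding PD-L1, by 2.05, whereas Gbp2, a guanylate binding protein gene, differed by 0.56 (SE 0.38, adjusted p = 0.176). Type I interferon genes went both ways, with 6 of 20 higher and 11 lower, and rescaling turned this to 10 higher and 5 lower and their median from -0.49 to 0.44 (camera adjusted p = 0.946, direction up, against a mean of -0.43). Isg15, a ubiquitin-like modifier gene of that list, rose by 1.17, while Ifi208 and Slfn1 were at -2.35 and -1.54. Effector and regulatory T cell genes rose in 9 of 15 cases and fell in 5 (camera adjusted p = 0.0474; adjusted p = 0.468 with an estimated correlation), and this call ended without adipocyte replicate 3 (adjusted p = 0.0555) or replicate 3 in every group (adjusted p = 0.0503). The list median was 1.06, and also 1.06 with the 2 members that had no read in unconditioned medium set at a floor of 3 reads per library.

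The 3 lipid lists had medians below 0 in adipocyte medium, and single genes went both ways. Plin2 (ENSMUSG00000028494), which encodes a lipid droplet coat protein, rose from 758 ± 18.9 to 3943 ± 627 normalized counts (log2 fold change 2.36, SE 0.13, adjusted p = 1.33e-08), Hilpda, a lipid droplet gene induced by hypoxia, by 2.27, and Cpt1a, for the entry step of long-chain fatty acids into mitochondria, by 1.08. The mitochondrial carrier gene Ucp2 was at -2.29, and the PPAR and fatty acid oxidation list as a whole held 7 genes higher and 15 lower of 22 (median -1.09, camera adjusted p = 0.798; 7 higher and 6 lower after rescaling). All 9 tested cholesterol synthesis and SREBP2 target genes, of 28 on the list, fell (camera adjusted p = 0.0552, 0.0423 with the mouse as a block and 0.555 with an estimated correlation). Among them were Sqle, for squalene epoxidase, from 2547 ± 265 to 756 ± 66.1 (log2 fold change -1.75, SE 0.11), and Hmgcs1, for the synthase of the mevalonate pathway, at -1.07. Of 10 fatty acid synthesis and LXR targets 9 fell and 1 rose (camera adjusted p = 0.159), with the desaturase gene Scd2 at -3.61, the sterol exporter genes Abca1 and Abcg1 at -1.93 and -1.54 and Mylip, a ubiquitin ligase gene, at -1.77. Genes of ATF4 targets and amino acid metabolism went both ways, 10 of 17 higher and 7 lower (camera adjusted p = 0.0577, and 0.424 with an estimated correlation; 10 higher and 2 lower after rescaling, adjusted p = 0.0255), with the stress transcription factor genes Atf4 and Atf3 up by 1.99 and 2.34 and the amino acid transporter chain gene Slc3a2 by 2.56. After rescaling by the median of ratios, 3 cholesterol genes and 5 LXR list genes were still lower, with 0 and 2 higher. The 5 oxidative phosphorylation genes tested, of 90 symbols on the list, were all lower on the deposited scale (median -0.92). After rescaling they had a median of 0.01 with 0 past the threshold.

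Cytoskeletal, adhesion and receptor genes fell more often than they rose on the deposited scale. Of 13 actin cytoskeleton genes 9 fell and 4 rose (camera adjusted p = 0.526), with the motor gene Myo1f at -1.89 and the actin capping gene Capg at -1.28. Integrin and adhesion genes were lower in 7 of 9 cases and higher in 2 (adjusted p = 0.349), with the integrin subunit genes Itga4 and Itgb7 at -1.94 and -1.48 and Itgb3 up by 1.10, and both microtubule genes that could be tested fell. Among 8 genes of T cell receptor signalling 6 fell and 2 rose (adjusted p = 0.349). The co-receptor gene Cd8a fell from 9534 ± 810 to 2167 ± 139 normalized counts (log2 fold change -2.14, SE 0.08), and the CD3 chain genes Cd3g and Cd3e were at -1.64 and -1.19. These directions are relative to the authors' scaling of the libraries. After rescaling 5 actin genes were lower and 4 higher, 2 adhesion genes were lower and 2 higher, and 0 microtubule genes were lower. The excess of falls thus ended for adhesion, while all 6 receptor genes stayed lower and the microtubule median turned from -0.93 to 0. Beta-actin, myosin heavy chain 9, coronin 1a and cofilin 1, chosen before the data were examined, are not in the sample table. The actin list holds 77 genes, of which 13 were tested. As the sample table holds only genes the authors called changed, the actin counts above describe those genes and not the core actin machinery.

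Proliferation genes were lower in 17 of 19 cases and higher in 2 (median -1.42; camera adjusted p = 0.0547, and 0.0479 with the mouse as a block), with the mitotic genes Ccna2 and Birc5 at -2.11 and -1.95. Rescaling left 10 lower and 2 higher with a median of -0.49 (camera adjusted p = 0.0311). With an estimated correlation, on the deposited scale, the camera adjusted p of this list was 0.636. Histone H4 genes rose. H4c18 and H4c17 were up by 5.30 and 5.27 and H4c3 by 4.26, with near-identical copies that make each of these 3 values uncertain. The lysosomal hydrolase gene Sgsh and the Ras association gene Rassf4 fell by 3.64 and 3.69 on the log2 scale. Quiescence and naive cell genes went both ways, 3 of 9 higher and 4 lower, with Igfbp4 up by 1.84 and Dapl1 at -2.10; their median of -0.05 and mean of -0.09 stood against a camera direction of up (adjusted p = 0.507), and rescaling gave 5 higher and 1 lower with a median of 0.87. Klf2, a transcription factor gene of resting T cells, was at 55286 ± 3597 and 53821 ± 9412 (log2 fold change -0.05, SE 0.12, adjusted p = 0.694), and rescaling put it at 0.87 (adjusted p = 9.17e-05). Chemokine and trafficking receptor genes split into 4 higher and 4 lower of 8, with Ccr8 up by 2.03 and Cx3cr1 at -1.98, NRF2 targets into 2 higher and 4 lower of 6, and both testable endoplasmic reticulum chaperone genes rose. Under rescaling the receptors were 5 higher and 2 lower, and the NRF2 targets 2 higher and 0 lower (median -0.13, against -1.05).

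Markers of cells that the selection should remove moved with adipocyte medium. All 11 tested B cell markers, of 22 on the list, fell (median -1.84; camera adjusted p = 0.115, and 0.0483 with the mouse as a block). Of 16 tested myeloid markers, from a list of 28, 14 fell against 1 that rose (camera adjusted p = 0.202). Under rescaling camera called both lists, down, at an adjusted p of 0.0281 and 0.0311. With an estimated correlation, on the deposited scale, the camera adjusted p was 0.627 and 0.654. The B cell receptor chain gene Cd79b was at -2.49, Csf1r, encoding a macrophage growth factor receptor, went from 920 ± 265 to 63.4 ± 24.6 normalized counts, and lysozyme gene Lyz2, which has a close paralog, from 3314 ± 1308 to 210 ± 108. Of 10 neutrophil markers 8 fell and 2 rose (camera adjusted p = 0.769). The 5 tested T cell markers, of 20 on the list, fell as well (median -1.54, adjusted p = 0.0572), so the lower markers in this selection were not limited to other cell types. The authors had listed 11 B cell, 15 myeloid, 10 neutrophil and all 5 T cell markers as changed in adipocyte medium. These counts thus do not show that the markers of any cell type fell as a class. After rescaling, 6 of 11 B cell, 10 of 16 myeloid, 5 of 10 neutrophil and 4 of 5 T cell markers were still lower. The single natural killer marker tested rose and the single erythroid marker tested, Car1, was at -1.70. Of 2 adipocyte genes 1 rose and 1 fell, and 0 stromal genes were in the sample table.

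In the limma fit 2787 of the 2868 genes were past an adjusted p of 0.05 in adipocyte against unconditioned medium, 969 higher and 1818 lower, and 540 changed at least 4-fold (205 higher, 335 lower). The median gene was at -1.03, and 2807 genes had the same sign in all 3 mice. A median of ratios over these selected genes moved all fold changes by 0.93 on the log2 scale and gave 1078 higher and 1047 lower. It brings the median of the selected genes near 0 (-0.11) by construction, so a near-even split follows whatever the true direction. The rescaled split therefore cannot tell whether the excess of lower genes comes from the authors' scaling. The directions above hold on the authors' scale. Adjusted over the list alone, the number of genes past the threshold was the same as over all genes in each fixed list of this comparison.

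**Figure D3:**
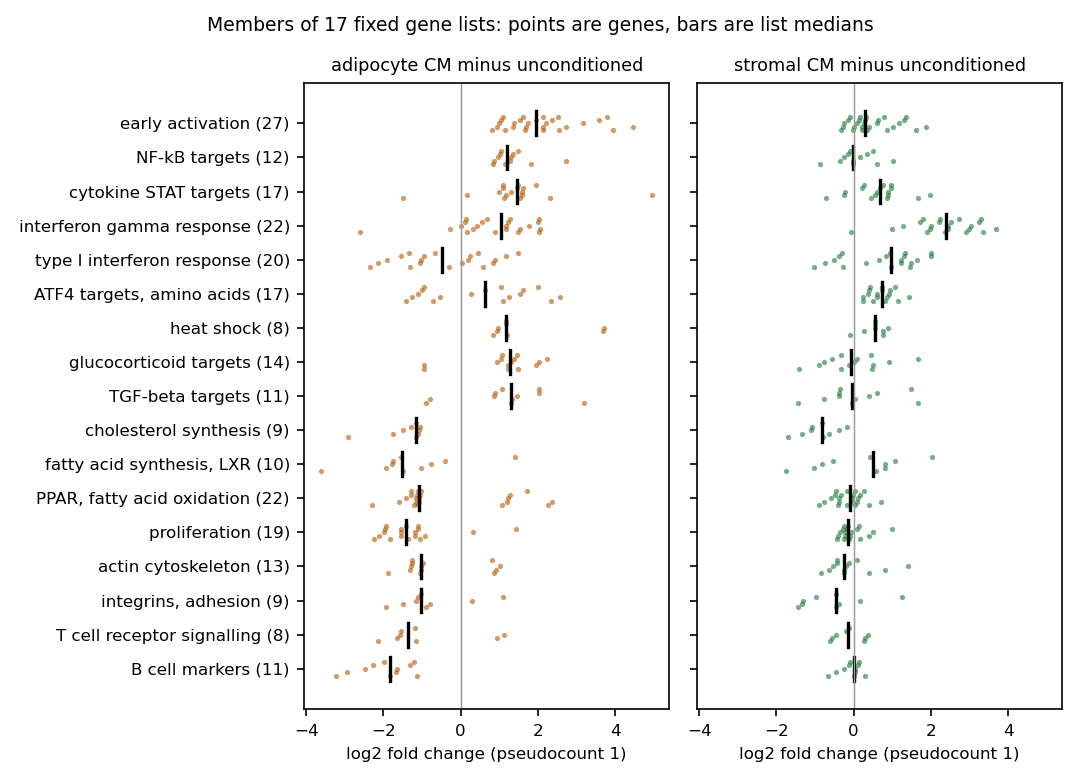
Log2 fold changes on the log2(normalized count + 1) scale (horizontal axes) of the tested members of 17 fixed gene lists in adipocyte (left) and stromal (right) against unconditioned medium. Each point is 1 gene, the black bars are list medians and the numbers in brackets count tested members; early activation genes have a median of 1.95 on the left and 0.30 on the right, interferon gamma genes 1.03 and 2.40, and rescaling turns the sign of the type I interferon median on the left and of the NF-kB, glucocorticoid, TGF-beta, PPAR, proliferation, actin and receptor medians on the right.

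The second comparison asked the same of stromal conditioned medium, and interferon gamma response genes led it. Gbp2 (ENSMUSG00000028270) went from 5950 ± 936 normalized counts in unconditioned medium to 65282 ± 31420 in stromal medium (mean ± SD, n = 3), a log2 fold change of 3.36 (SE 0.38, limma adjusted p = 1.42e-05). Socs1, for an inhibitor of interferon signalling, went from 2214 ± 212 to 8678 ± 260 (log2 fold change 1.97, SE 0.11, adjusted p = 3.47e-07). Of 35 genes on the interferon gamma list 22 were tested. The authors had already listed 21 of these 22 as changed in stromal medium, so calls among them repeat that selection. Here 21 rose and 1 was not past the threshold, with a median of 2.40 (camera adjusted p = 5.76e-14; adjusted p = 0.504 with an estimated correlation). Gbp11, Gbp5 and the immunity-related GTPase gene Iigp1 rose by 4.84, 3.25 and 2.98 and the serpin gene Serpina3g by 2.91. Gbp6 and Gbp10, at 3.30 and 3.03, share exons with another annotated gene, and the odorant receptor gene Olfr56, at 3.84, shares exons with the interferon-induced gene Ifi47, so these 3 values cannot be assigned to 1 gene.

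Type I interferon genes rose in 13 of 20 cases and fell in 6 in stromal medium (median 0.96, camera adjusted p = 0.00139; adjusted p = 0.504 with an estimated correlation), with the antiviral genes Oasl2, Rtp4 and Isg15 up by 1.49, 2.00 and 1.46. Of 17 cytokine STAT targets 12 rose and 1 fell (adjusted p = 1.15e-04; adjusted p = 0.504 with an estimated correlation), led by Socs1 and by the kinase gene Pim2 at 1.67. ATF4 target and amino acid genes rose in 16 of 17 cases, by a median of 0.73 (adjusted p = 6.44e-08; adjusted p = 0.145 with an estimated correlation). Among them were the transaminase gene Gpt2 at 1.43, the serine synthesis gene Psat1 at 1.14, the mitochondrial folate gene Mthfd2 at 1.06 and the amino acid transporter gene Slc7a5 at 0.93. Ribosome biogenesis genes rose in 8 of 10 cases (adjusted p = 8.9e-04; adjusted p = 0.38 with an estimated correlation), with the spermidine synthase gene Srm at 0.92. Heat shock genes rose in 6 of 8 cases and p53 target and BCL2 family genes in 8 of 13 with 1 lower, both at a camera adjusted p of 0.00432 and an adjusted p = 0.504 with an estimated correlation, among them Cdkn1a at 1.67 and the survival gene Bcl2 at 1.47. Early activation genes rose in 12 of 27 cases and fell in 0 (median 0.30, adjusted p = 7.19e-04; adjusted p = 0.632 with an estimated correlation), and rescaling gave 19 higher and 0 lower (median 0.66). Among them Ifng was at 1.61 and Gzmb at 1.31 on the deposited scale, whereas Nr4a1 stood at -0.09 (SE 0.20, adjusted p = 0.703). Without replicate 2 in every group Nr4a1 was at -0.27 (adjusted p = 0.0373).

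Cholesterol synthesis genes were lower in stromal medium too. Of 9 cholesterol synthesis genes 8 fell and 0 rose (median -0.83, camera adjusted p = 0.00625; adjusted p = 0.504 with an estimated correlation), with Sqle at -1.32 and Hmgcs1 at -0.83, and 6 of the 9 stayed lower after rescaling. In the fatty acid synthesis and LXR list 5 of 10 genes rose and 3 fell, so the list was not called (adjusted p = 0.281; 6 higher and 3 lower after rescaling). Scd2 went from 3147 ± 389 to 12875 ± 1265 normalized counts (log2 fold change 2.03, SE 0.23), and the sterol exporter genes Abcg1 and Abca1 rose by 1.08 and 0.80. Of 22 PPAR and fatty acid oxidation genes 1 rose and 9 fell (median -0.10, adjusted p = 0.74), whereas rescaling gave 10 higher and 2 lower (median 0.25). Acox3 and Cpt1a were at -0.91 and -0.76 and Plin2 at 0.10 (SE 0.13, adjusted p = 0.511; 0.46 and adjusted p = 0.0109 after rescaling). Glycolysis genes rose in 5 of 9 cases and fell in 1 (adjusted p = 0.0783, 0.0471 with the mouse as a block and 0.545 with an estimated correlation). NRF2 targets rose in 4 of 6 and fell in 1 (adjusted p = 0.0853, 0.0489 under rescaling and 0.504 with an estimated correlation), and 2 of 5 oxidative phosphorylation genes fell with 0 higher (median -0.11; 3 higher and 0 lower under rescaling, median 0.25).

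Of 9 integrin and adhesion genes 7 were lower in stromal medium and 1 was higher, a list that was not called (camera adjusted p = 0.113), with Itgae and Itgb7 at -1.44 and -1.34 and Itgb3 up by 1.25, and rescaling gave 4 lower and 2 higher. The resting-cell factor Klf2 was at -0.99, the adhesion receptor gene Adgre5 fell from 28562 ± 2139 to 7793 ± 1156, and Scaper, Slc25a35 and Rgs11 were at -2.38, -2.26 and -1.98. Quiescence genes split into 3 higher and 4 lower of 9 and trafficking receptors into 1 higher and 3 lower of 8, with Cxcr4 up by 0.47 and S1pr4 at -1.01. Rescaling gave 4 higher and 4 lower for quiescence genes and 4 higher and 2 lower for receptors, and turned both medians, -0.21 and -0.05, above 0. Of 13 actin genes 3 rose and 6 fell (adjusted p = 0.74; median -0.25), and 5 were higher and 2 lower under rescaling (median 0.11), with Marcksl1 up by 1.41 and the GTPase gene Rac2 at -0.64, and both microtubule genes fell. T cell receptor genes moved little: 3 of 8 were higher and 4 lower, within -0.61 and 0.37, Cd3e at -0.61 and Cd8a at 0.30, and rescaling gave 4 higher and 1 lower and turned their median from -0.16 to 0.20.

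The markers of other cells gave few calls in stromal medium. Of the tested markers, the authors had listed 11 B cell, 15 myeloid, 10 neutrophil and 5 T cell markers as changed in adipocyte medium. In stromal medium they had listed 0, 1, 0 and 0, so the selection favoured few calls here. By limma 0 of 11 B cell markers were past the threshold, with 1 at an unadjusted p under 0.05 and 0 by edgeR and by DESeq2, and their median was 0.01. Of 16 myeloid markers 2 rose and 5 fell, of 10 neutrophil markers 2 fell and of 5 T cell markers 1 rose and 2 fell (camera adjusted p = 0.935, 0.74 and 0.74). Rescaling gave 3 myeloid markers higher and 2 lower and 3 T cell markers higher and 1 lower, with the medians of -0.28 and -0.12 turned above 0. Adjusted over the list alone, 0 neutrophil markers were past the threshold in limma, against 2 over all genes. Klrb1f, a gene of the natural killer receptor family, nonetheless rose by 3.48 and the single erythroid marker, Car1, by 1.47. The single natural killer marker of the fixed list was at 0.31 and not past the threshold, and 1 of 2 adipocyte genes rose. NF-kB targets split into 4 higher and 2 lower of 12, TGF-beta targets into 3 and 4 of 11, glucocorticoid targets into 5 and 5 of 14, effector genes into 5 and 4 of 15 and proliferation genes into 3 and 1 of 19, none of them called by camera. For these 5 lists rescaling gave 7 and 1, 6 and 2, 7 and 3, 8 and 3, and 5 and 0. For NF-kB, TGF-beta, glucocorticoid, proliferation, trafficking receptor and myeloid genes camera gave a direction of up against medians of -0.02, -0.05, -0.06, -0.14, -0.05 and -0.28, and for B cell markers up against a mean of -0.08. Rescaling turned the first 4 of these medians and the trafficking and myeloid medians above 0. The cytotoxic gene Prf1 of the effector list was at -1.81, and both testable chaperone genes of the endoplasmic reticulum rose.

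In the limma fit 1655 genes were past the threshold in stromal against unconditioned medium, 606 higher and 1049 lower, and 79 changed at least 4-fold (63 higher, 16 lower). The median gene was at -0.17. Rescaling moved all fold changes by 0.36 on the log2 scale and turned the split to 1129 higher and 562 lower, and a null of 1.5-fold in DESeq2 left 515 genes (178 higher, 337 lower). Adjusted over the list alone, 11 early activation, 15 STAT target, 9 ribosome biogenesis and 9 p53 genes were past the threshold, and 21 interferon gamma and 16 ATF4 target genes, as over all genes.

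The third comparison tested the difference between the conditioned media directly. The desaturase gene Scd2 (ENSMUSG00000025203) showed the largest fall among the named genes, with 271 ± 118 normalized counts in adipocyte medium against 12875 ± 1265 in stromal medium (mean ± SD, n = 3; log2 fold change -5.65, SE 0.23, limma adjusted p = 7.12e-09). Interferon gamma response genes were lower in adipocyte than in stromal medium in 20 of 22 cases, with a median of -1.53 (camera adjusted p = 0.0321; adjusted p = 0.669 with an estimated correlation), among them Gbp2 and Socs1 at -2.80 and -1.81, and rescaling left 13 lower and 2 higher. The authors had listed 21 of these 22 as changed in stromal medium and 10 in adipocyte medium, so the selection favoured this direction. The Ifng transcript itself was higher in adipocyte medium, at 1809 ± 273 against 354 ± 30.6 (log2 fold change 2.34, SE 0.16). Type I interferon genes were lower in 17 of 20 cases and higher in 2 (adjusted p = 0.0199; adjusted p = 0.497 with an estimated correlation). Rescaling left 11 lower and 2 higher and moved their median from -0.92 to -0.35. Ifit3b was at -3.13, while Isg15 was at -0.29 (adjusted p = 0.0877, 0.0487 with the mouse as a block and 0.0371 without adipocyte replicate 1).

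Activation genes were higher in adipocyte medium than in stromal medium in 26 of 27 cases and lower in 1, the latter being Irf8 at -0.36 (median 1.72, camera adjusted p = 8.55e-09). The authors had listed all 27 as changed in adipocyte medium and 4 in stromal medium, so the selection favoured a larger change in adipocyte medium. The other lists of this paragraph also had more members listed for adipocyte than for stromal medium. Nr4a1, Il4, Il21 and Cxcl2 differed by 2.22, 4.00, 4.00 and 4.12, and the phosphatase gene Dusp8, lower in stromal and higher in adipocyte medium than in unconditioned medium, by 4.27. NF-kB targets were higher in 12 of 12 cases (adjusted p = 2.93e-05), TGF-beta targets in 10 of 11 (adjusted p = 7.28e-04), heat shock genes in 8 of 8 and STAT targets in 14 of 17 with 3 lower (adjusted p = 0.00406 for both). Glucocorticoid targets were higher in 12 of 14 cases with 1 lower (adjusted p = 5.53e-04), among them the small GTPase gene Rhob at 2.89, and effector genes in 10 of 15 with 3 lower (adjusted p = 0.0139). Glycolysis genes were higher in 7 of 9 cases and lower in 2 (adjusted p = 0.0474), a call that ended under rescaling (adjusted p = 0.0726) and without adipocyte replicate 1 or 2 or stromal replicate 3 (adjusted p = 0.0572, 0.0538 and 0.0577) or replicate 2 in every group (adjusted p = 0.0586). With an estimated correlation the adjusted p was 0.497 for each list of this paragraph.

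Lipid genes differed in both directions between the media. Plin2, Hilpda and Cpt1a were higher in adipocyte than in stromal medium by 2.26, 2.60 and 1.84, whereas Abca1, Abcg1 and Mylip were at -2.73, -2.62 and -2.35. The serine synthesis genes Psph and Psat1 were at -2.03 and -1.85, with 8 ATF4 targets higher and 9 lower of 17 (median -0.43 against a camera direction of up, adjusted p = 0.764; 8 higher and 7 lower under rescaling, median 0.14). Proliferation genes were lower in 18 of 19 cases and higher in 1 (camera adjusted p = 0.00751; adjusted p = 0.497 with an estimated correlation). B cell markers were lower in 11 of 11 cases (adjusted p = 0.0452), a call that ended without adipocyte replicate 2 (adjusted p = 0.0538) or stromal replicate 1 (adjusted p = 0.055), and T cell markers in 5 of 5 (adjusted p = 0.0365). With an estimated correlation the adjusted p was 0.497 for both marker lists. Myeloid markers were lower in 13 of 16 cases and higher in 1 (camera adjusted p = 0.102, 0.0358 with the mouse as a block, 0.0326 under rescaling and 0.57 with an estimated correlation). The authors had listed 18 proliferation genes and 11 B cell, 5 T cell and 15 myeloid markers as changed in adipocyte medium. In stromal medium they had listed 1, 0, 0 and 1, so the selection favoured a larger change of these lists in adipocyte medium. The actin list held 2 genes higher and 10 lower of 13 (median -0.62, adjusted p = 0.222; 3 higher and 5 lower after rescaling, median -0.05), with Tpm4 up by 1.28 and Evl at -1.35. The p53 target gene Phlda3 was at -4.08 and Klrb1f at -4.98. Klf2 and Adgre5, low in stromal medium, were higher in adipocyte medium by 0.94 and 1.79.

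In all, 2609 genes were past the threshold between adipocyte and stromal medium, 968 higher and 1641 lower in adipocyte medium, and 362 changed at least 4-fold (132 higher, 230 lower). The median gene was at -0.60. Rescaling moved fold changes by 0.57 on the log2 scale and gave 1172 higher and 1091 lower, and a null of 1.5-fold in DESeq2 left 1574 genes (558 higher, 1016 lower). Cd3e, at -0.58 with an adjusted p of 1.57e-05, was at -0.02 after rescaling (adjusted p = 0.878).

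Both conditioned media were compared with the same unconditioned samples, and 1421 genes were past the threshold in both with the same sign, 478 higher and 943 lower. After rescaling there were 1040, with the split reversed to 758 higher and 282 lower. Independent lists of these sizes would share 205 higher and 665 lower genes, and these genes were selected for changing. Unchanged groups simulated against the shared controls gave a median of 0 such genes and at most 1 in 100 sets, as they must with hardly any calls, so this count is no measure of a shared response. Opposite signs were seen for 70 genes higher in adipocyte and lower in stromal medium and for 88 the other way, against 354 and 384 for independent lists. The correlation of log2 fold changes across genes, which are not independent replicates, was 0.538 (Spearman 0.516), which lies within the simulated range, with a median of 0.503 and a highest value of 0.58. The covariance was 0.754, where noise of the shared controls alone gave 0.0259. The highest simulated covariance was 0.0323, which argues against noise of single genes in the shared controls as the source of the excess. A shift common to all unconditioned libraries was not simulated, and the controls could not be split with 2 libraries in each part. Such a shift may thus account for some of the excess.

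The authors' 4 gene clusters followed these responses and were built on the same samples. Their cluster 1, with 913 tested genes, held 910 genes higher in adipocyte medium and a median of 1.29 there and 0.30 in stromal medium. Cluster 2, with 1611 tested genes, held 1610 genes lower in adipocyte medium (medians -1.38 and -0.36). Cluster 3, with 222, held 221 genes lower in stromal medium (medians -0.79 and -1.22), and cluster 4, with 122, held 114 genes higher in stromal medium (medians 0.27 and 1.54).

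The authors' deposited table for adipocyte against unconditioned medium listed 3181 genes, 1211 higher and 1970 lower, and their table for stromal against unconditioned medium 598 genes, 232 higher and 366 lower. The authors' deposited tables shared 284 genes, 273 of them with the same sign. For the genes that could be tested here, the sign matched in 2641 of 2641 and 472 of 472 cases against the authors' deposited tables, and 2640 and 468 were past the threshold. Both rest on the same samples and the same scaling, so this match follows by construction and is no separate evidence. The authors' deposited tables also held 540 and 105 genes that the sample table does not list, for which no sample values were analysed here.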

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

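The run without stromal replicate 1 and the rescaling of gene counts were planned as alternatives. Their use here as tests of a cause, and all other tests in this part, were chosen after the results they measure were seen. The authors' deposited tables hold genes outside the sample table, and among them are signals that no comparison above used. In their adipocyte table the ribosomal RNA gene Rn18s was at 1.17 on the log2 scale and the mitochondrial ribosomal RNA gene mt-Rnr2 at 1.31, whereas mt-Nd3, which encodes a subunit of mitochondrial complex I, was at -1.77. All 18 small nuclear and nucleolar RNA genes listed there were higher in adipocyte medium, and all 4 mitochondrial tRNA genes listed there were lower. All 36 immunoglobulin segments listed there were lower. Of the genes in the authors' deposited table for stromal medium, 56 had a mean under 5 normalized counts and a log2 fold change beyond 10 in size.

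Replication-dependent histone genes were higher in adipocyte medium, 40 of 41 with a median log2 fold change of 3.12. More cells in S phase would raise proliferation genes with them, but the proliferation list had a median of -1.42, and of -0.49 after rescaling with 10 of 19 genes lower and 2 higher. The authors' normalization, with 1 factor per library, moves all genes alike and is argued against as the source of the distance of 4.17 between the histone median and that of the other genes. How much of the rise itself comes from it stays open, since rescaling raises every change by 0.93 and the 41 histone genes higher after it decide nothing. More RNA without a poly(A) tail in the libraries stays open too, as all 18 listed small nuclear and nucleolar RNA genes, which lack the tail, rose in the authors' deposited table while the 4 mitochondrial tRNA genes fell.

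B cell markers were lower in adipocyte medium in 11 of 11 cases, although the negative selection should remove B cells. The authors had listed all 11 as changed in adipocyte medium, so the count is over genes selected for this change. The authors' normalization is argued against as the whole cause, since 6 markers were still lower after rescaling. Fewer B cells in the adipocyte medium samples would lower all markers alike, and 2 of 11 departed from the list mean within samples, among them Cd74 at 0.85. Without the class II genes and Cd74, which other cells also express, 2 of 7 departed, among them Cd79a at 0.63, so fewer B cells and lower expression in the same B cells cannot be told apart: RNA of the remaining cells may have changed too. A first version of this test, on the spread of the fold changes, decided nothing and was replaced.

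Interferon gamma response genes were higher in stromal than in adipocyte medium, although Ifng transcript was higher in adipocyte medium by 2.34 on the log2 scale. The level of Ifng transcript in the cells is thus argued against as the cause, as the list median was -1.53 in adipocyte against stromal medium, and -0.96 after rescaling. These values are the pattern that raised the question and not a separate test of it. The selected members of this list also came mostly from the authors' stromal table. A single library is argued against too, since 18 of 22 genes were still lower without stromal replicate 1, the library with the highest Gbp2. Interferon or an inhibitor carried by the media may account for the difference, and this was not tested.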

How the results depend on the processing

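The runs of edgeR and DESeq2 and the rescaled list tests were chosen after seeing the data. More genes were lower than higher in each comparison under every alternative run on the deposited scale. Fewer were lower than higher under rescaling, which is built on the selected genes alone and cannot show which direction is right. A smaller set passed where a minimum effect was asked for, by construction. In stromal against unconditioned medium a DESeq2 null of 1.5-fold left 515 genes and a fold of at least 1.5 left 1039, in adipocyte against stromal medium the DESeq2 null left 1574, and the genes shared by both responses fell to 303 and 846. With an estimated correlation camera called 0, 0 and 0 lists, with 1, 2 and 0 at an unadjusted p under 0.05, where it had called 11, 9 and 13. Rescaling by the median of ratios gave 2125, 1691 and 2263 genes, 1040 shared genes and 15, 10 and 13 lists, 3 of the 15 down where none of the 11 was. It reversed the sign of Pecam1 (0.04), Ndufs8 (0.01), Ndufv1 (0.12), Ndufb9 (0.04), Cdk4 (0.01) and Klf2 (0.87) in adipocyte against unconditioned medium, since it shifts every gene by 0.93. Leaving out 1 library, or 1 replicate number in every group, gave 2765 to 2800 genes in adipocyte and 1335 to 1772 in stromal against unconditioned medium, 2450 to 2599 between the conditioned media and 1133 to 1506 shared genes; lists called were 10 to 13, 9 to 10 and 12 to 14. Depth limits genes near the minimum mean of 1, and 3 mice limit small changes: limma recovered 61.2% to 68.7% of 1.5-fold changes in simulated data.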

Other observations

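All tests in this part were chosen after the results they measure were seen. Interleukin and interleukin receptor genes, grouped by the symbol stem Il, rose in adipocyte medium in 17 of 23 cases and fell in 6 (median 2.25; Fisher's exact test, adjusted p = 0.0059 over 31 stems), and 19 were higher and 1 lower after rescaling. Il17a, a cytokine of type 17 helper cells, had 0 reads in unconditioned medium and 73.7 ± 39.2 normalized counts in adipocyte medium, at least 23.1-fold higher against a floor of 3 reads per library. Il13, a type 2 cytokine, was at least 3.88-fold higher by the same floor. Protein phosphatase genes (stem Ppp) rose in 8 of 10 cases and fell in 2 (adjusted p = 0.047, exact test). Zinc finger genes (stem Zfp) fell in 62 of 75 cases and rose in 13 (adjusted p = 0.019, exact test), and 28 were lower after rescaling.

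In stromal medium all 10 guanylate binding protein genes rose (adjusted p = 0.0013, exact test), several of them with close paralogs. In adipocyte medium 3 of them rose and 0 fell, and after rescaling all 10 were higher in both media. In stromal medium 17 transmembrane protein genes of the stem Tmem fell with 0 higher (adjusted p = 0.0085, exact test), though 3 were higher and 9 lower after rescaling. Among the genes that the sample table does not hold, the authors' deposited adipocyte table has the small RNA host genes Snhg12, Snhg1 and Zfas1 at 2.36, 2.06 and 1.71 on the log2 scale and Gas5 at 1.10.

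Genes without introns as a class were tested as another explanation for the histone rise. Outside the histone clusters single-exon genes rose in 31.6% of cases and other genes in 34%, an odds ratio of 0.9 (95% interval 0.62 to 1.29; Fisher's exact test, two-sided p = 0.6), which argues against it. The bound used to read this test was changed from the p-value to the interval after the p-value was seen.

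Other splits of the 6 samples of each comparison were counted in limma. The real split gave 2787 genes in adipocyte against unconditioned medium, 1655 in stromal against unconditioned medium and 2609 between the conditioned media, and the highest other split gave 0 in each (28, 48 and 25 at an unadjusted p under 0.05). Thus 1 of 10 splits gave as many genes in each comparison, and 10 splits are too few for a share under 0.05. The numbers pair the samples, and 4 splits part all 3 pairs, the highest other of which gave 0. Every other split mixes both media within each part, which adds the difference between media to the spread. Few calls in those splits follow by construction, so they give no support to the real split.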
